A study of Bos taurus with 12 samples.

How the data were processed

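The samples were biopsies of the endometrium, the inner lining of the uterus, taken from Japanese-Black cows on day 15 of the estrous cycle in summer and in autumn. Each season was sampled in the horn on the side of the corpus luteum (CL side), the ovarian body that secretes progesterone, and in the opposite horn (non-CL side). Per the labels' protocols, 400 ng of total RNA per sample was amplified and labelled with the dye Cy3. Every sample was hybridised alone to a 1-colour Agilent bovine array, which gave 12 arrays in 4 groups of 3. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates of a group came from separate animals, and p-values then measure only the spread between these samples.

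The deposited files were the scanner output of each array. Per the file headers, images were read with Feature Extraction 9.5.1.1, and the submitters' processing notes name version 9.5. The processed signal is a spot intensity on a linear scale that, per the file headers, had been background-subtracted and detrended within the array and not scaled between arrays. It can be 0 or below, which held for 802 to 2092 signals per array. Mean spot and local background intensities, as deposited, entered only 1 alternative. The authors also deposited a table of log2 values for the same arrays, with scale and centring unstated. Set against the scanner values of the same array, its columns correlated at 0.970 to 0.995, ran in the same direction, lay close to 0 at the 75th percentile and were not centred per probe. Its column medians lay between −2.79 and −2.61, and the treatment of low signals stayed unknown. It was used as an alternative.

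The array held 15208 non-control probes. The reference gene table of the ARS-UCD2.0 assembly, used for names only, or the files themselves gave a symbol to 7094 probes and 6762 symbols in all. Another 56 probes had only a locus name and 8058 stayed unnamed. Of the symbols, 226 had several probes, and the probe with the highest mean signal over the 12 arrays stood for the gene. No coordinates are given, because the assembly behind the array is not given in the sources used here.

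Each array's processed signals were divided by their 75th percentile over non-control probes and put on the log2 scale. A floor of −7.28 was set after scaling, the highest over the arrays of the lowest signal well above background. The floor was not part of the design fixed before the data were examined and was added because signals at or below 0 have no logarithm. It held 2.06% of the kept values, and at most 5.11% of 1 array (CL-side autumn replicate 1). Control spots were left out, and 464 values with an outlier flag were set to missing. Probes well above background on all arrays of at least 1 group were kept, which left 12404 probes and removed 2804. Of the kept probes, 11189 were well above background on all 12 arrays, and 5844 genes with a symbol were tested. The number of arrays limits the precision of every value.

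Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05 on the adjusted p. All 12 arrays entered a single fit of 4 group means with 8 residual degrees of freedom. For the season change over both sides, the log2 values of the same-numbered horns of a season were averaged first, which left 6 means and 4 residual degrees of freedom. Errors are standard errors (SE) of these fits unless named as SD, tests were two-sided, and a p given as unadjusted is limma's moderated p. A probe well above background on no array of a group gave only a bound there. The bright group's mean was then set against the dim group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background.

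A family of 33 gene lists, of pathways, secreted products and cell type markers, was fixed before the data were examined, together with the design and the rule for naming genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists of a comparison, with camera at an estimated correlation and fry beside it. Fry tests whether the genes of a list move, on balance, in 1 direction, or with its mixed p in either direction, and compares a list with no other genes. For the list tests a missing spot was filled with the fitted value, which held for 15 of the 710 list genes and leaves such genes no residual there. Genes measured on fewer than 50% of the values compared were left out, p-values of single members used measured spots alone, and the tests were run again on genes measured on all 12 arrays. A list needed at least 5 measured genes. A list's score on an array was the mean over its genes of the log2 difference from the 12-array mean. Named were, with no gene past the threshold, the genes with the smallest unadjusted p, up to 5 per direction. Also named were up to 4 members with the smallest p of each list that passed, and 12 genes fixed for the season comparisons. Some genes that the rule names are not reported here. With 3 arrays against 3, the smallest p of an exact permutation test is 0.1.

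Same-numbered samples deviated together from their group means across all probes, which points to a pairing by number. The main fit of the group means did not use that pairing, and only the season change over both sides averaged same-numbered horns. Between the horns of a season the correlation of these deviations was 0.27 to 0.50 in summer and 0.14 to 0.38 in autumn. Between the seasons it was 0.11 to 0.24 on the CL side and 0.16 to 0.35 on the non-CL side. The pairing comes from the data, as no label says what a number marks. The fit with the replicate number as a block was an alternative. Without the block, variation shared by the horns stays in the SE and p of the comparisons of sides. With it, more probes had an unadjusted p under 0.05 in these comparisons. The counts were 422 against 175 in summer, 526 against 230 in autumn and 452 against 205 over both seasons. All lay below the 619 expected by chance. All summer arrays and both autumn replicate 1 arrays lay on slide 1 (scan 1), and the autumn replicates 2 and 3 of both sides on slide 2 (scan 2). Slide was tested as a block and by the arrays of the first slide alone, which hold 3 summer arrays and 1 autumn array per side. CL-side summer replicate 2 was a dim array, and every count was also run without it, as an alternative added after the data were seen. For the season change over both sides, summer number 2 was then its non-CL-side array alone.

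Other alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, the authors' log2 values, no filter and a stricter filter on dim probes, outlier-flagged spots kept, a variance trend with robust eBayes, an adjusted p threshold of 0.1, only the arrays compared, and each replicate left out in turn. Added after the data were seen were a floor 1 log2 unit higher, array weights, list genes measured on all 12 arrays, the replicate number as a block across seasons, and slide settings for the comparisons of sides. The block across seasons was fitted to all 12 arrays and did not average the horns. The replicate block of a season comparison used only the arrays or means compared. The fits were tested on simulated data, with 5 simulations per comparison on 12403 probes, 200 of them changed. The simulated values varied independently between probes and arrays, with no variation shared by horns, slides or genes. In the season comparison on the CL side, 35.2% of 2-fold and 85.8% of 4-fold changes passed. The shares were 40.4% and 82.0% for the season on the non-CL side, and 57.0% and 94.2% for the mean of the sides. They were 39.4% and 86.8% for the sides in summer, 40.0% and 86.4% in autumn, and 68.2% and 95.4% for the mean of the seasons. For the difference between the season changes of the sides they were 8.6% and 64.6%. All these shares hold for independent noise. In the real samples same-numbered horns deviated together, so the shares for the mean of the sides may be too high. In a difference between the sides such shared variation drops out. The other shares may be off too, in a direction that was not tested.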

Results

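Gene expression was measured in 12 endometrium biopsies of Japanese-Black cows on day 15 of the estrous cycle, 3 each from the CL side and the non-CL side in summer and in autumn. The 75th percentile of the processed signal was 3516 to 4418 on 11 arrays and 2007 on CL-side summer replicate 2, called the dim array. The dim array had a median correlation of 0.928 with the other arrays, whereas any pair of the other 11 arrays correlated at 0.972 or more. Between 79.2% and 84.1% of the probes were well above background on each array. Log2 values are relative to the array's 75th percentile, and changes are summer minus autumn or CL side minus non-CL side.

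The first comparison asked how the CL-side endometrium differed between summer and autumn. No probe passed the threshold, and lists were called only at the preset correlation, defence and epithelial lists higher and stroma lower in summer. LAP, lingual antimicrobial peptide, a beta-defensin of bovine epithelia, had a log2 signal of −1.04 ± 2.18 (SD, n = 3) in summer and −6.60 ± 0.68 (SD, n = 3) in autumn, a change of 5.56 ± 1.05 (SE). PIGR, the receptor that carries polymeric immunoglobulins across epithelia, had a change of 4.38 ± 0.89, and RNF182, a ubiquitin ligase, and GLB1, the lysosomal beta-galactosidase, had changes of 1.1 ± 0.17 and 0.96 ± 0.18. MOBP had a change of 1.30 ± 0.27. On the lower side stood SRPX2 (−1.39 ± 0.26), BCHE, butyrylcholinesterase (−1.59 ± 0.34), IGFBP6, which binds insulin-like growth factors (−1.49 ± 0.33), the histone variant gene MACROH2A2 (−0.66 ± 0.16) and RCN3 (−0.70 ± 0.17). For these 10 genes the summer and autumn arrays did not overlap, and limma's adjusted p was 0.484 or 0.496. Chance gives no overlap for 10% of all genes with 3 arrays against 3. These genes were picked by the smallest p, so their lack of overlap is no separate support. MOBP in autumn and BCHE in summer were well above background on 2 of 3 arrays. With the authors' values, whose treatment of low signals is unknown, the changes were −0.071 for RNF182, −0.022 for MOBP, 0.31 for GLB1, −0.53 for BCHE and 3.59 for LAP, so those of RNF182 and MOBP depend on the source of the values.

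At the preset correlation the list of cytokines, chemokines and innate defence was higher in summer on the CL side, with a median log2 change of 0.52 over 44 genes (camera adjusted p = 1.37e-05), 37 of them higher. With an estimated correlation the adjusted p was 0.325 for this list, for granulocytes and for T and NK cells. TAP, tracheal antimicrobial peptide, had a change of 4.60 ± 1.31, the neutrophil chemoattractant gene CXCL2 3.58 ± 1.05 and S100A8, a calcium-binding protein abundant in neutrophils, 1.99 ± 0.47. S100A8 also stood in the list of granulocytes and mast cells (median 0.77 over 10 genes, adjusted p = 0.00780), with S100A12 at 1.33 ± 0.49, the lactoferrin gene LTF at 3.35 ± 1.45 and the chemokine receptor gene CXCR1 at 2.10 ± 0.90. These lists share 3 tested genes. T and NK cell markers had higher values (median 0.57 over 19 genes, 18 of them higher, adjusted p = 9.70e-05), among them CD69 at 1.07 ± 0.27, GNLY at 1.43 ± 0.41, IL2RG at 0.62 ± 0.24 and KLRB1 at 1.36 ± 0.57. Adjusted over the list alone, 2 members of the cytokine list, 1 of the granulocyte list and 0 of the T and NK cell list passed. Without the dim array the medians were 0.26, 0.45 and 0.46, and the changes of CXCL2, LTF, GNLY and KLRB1 were 2.14, 1.87, 0.95 and 0.83. With the authors' values the medians were 0.24, 0.46 and 0.13, and TAP had 2.90, CXCR1 0.63, IL2RG 0.061 and KLRB1 0.13.

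Epithelial lists were higher on the CL side in summer at the preset correlation. The adjusted p with an estimated correlation was 0.347 for epithelium, 0.501 for ciliated epithelium, and 0.325 for squamous epithelium and for the transporters. The median change was 0.65 for 23 epithelium markers (adjusted p = 4.71e-05), 20 of them higher, with the protease inhibitor gene SPINT1 at 1.24 ± 0.34, LAMB3 at 1.1 ± 0.41, AP1M2 at 0.60 ± 0.23 and the mucin gene MUC1 at 1.11 ± 0.44. It was 1.24 for 9 markers of ciliated epithelium (adjusted p = 0.00536), with the tektin genes TEKT1 at 1.89 ± 0.62 and TEKT2 at 1.27 ± 0.54, ROPN1L at 1.66 ± 0.73 and DNAI1, a dynein chain of cilia, at 1.24 ± 0.61. It was 0.55 for 7 markers of squamous epithelium, a list set up for tissue of the cervix and vagina (adjusted p = 0.00349). Among them were the keratin genes KRT15 at 5.11 ± 1.15 and KRT5 at 2.01 ± 0.74, TGM1 at 0.55 ± 0.23 and PKP1 at 0.87 ± 0.46. The squamous score was 0.79, 1.57 and 0.15 on the CL-side summer arrays and between −0.62 and −0.36 on the CL-side autumn arrays. Among 35 transporters of amino acids, glucose and ions (median 0.47, adjusted p = 0.00284) were the amino acid transporter gene SLC6A14 at 2.18 ± 0.64, the water channel genes AQP3 at 2.60 ± 0.82 and AQP5 at 2.66 ± 0.91, and ATP1B1 at 1.01 ± 0.35. Counted as adjusted over the list alone, 1 member of the squamous list and 0 of the other lists here passed. When the dim array was left out, the medians were 0.46, 0.77, 0.38 and 0.50, the call for ciliated epithelium ended (adjusted p = 0.0510), and AQP3, AQP5, SLC6A14 and KRT5 had changes of 1.34, 1.30, 1.32 and 1.0, and LAMB3, MUC1 and TEKT2 0.70, 0.64 and 0.77. The call for ciliated epithelium also ended without CL-side autumn replicate 1 (0.91, adjusted p = 0.0501). Over 22 alternatives, the estimated correlation aside, the squamous median ran from 0.31 to 0.70, and the call ended in 1. PKP1 had 0.35 without CL-side summer replicate 1 and DNAI1 1.91 without CL-side autumn replicate 3. With the authors' values the median of the transporters was 0.14, and TEKT1 had 0.59, DNAI1 0.044 and KRT5 0.53. On the first slide alone, with 3 summer arrays and 1 autumn array, the calls for epithelium (median 0.30, adjusted p = 0.114) and the transporters (0.40, adjusted p = 0.0806) ended.

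Stroma markers were lower on the CL side in summer at the preset correlation, all 17 of them with a change below 0 and a median of −0.81 (adjusted p = 9.05e-10). Camera with an estimated correlation gave an adjusted p of 0.325 for stroma and the cell cycle and 0.347 for the extracellular matrix. COL1A1, a chain of type I collagen, had a change of −1.53 ± 0.39, OGN −1.60 ± 0.44, THY1 −1.06 ± 0.31 and PDGFRA, a growth factor receptor of fibroblasts, −1.47 ± 0.48. The extracellular matrix list, which shares 5 tested genes with the stroma list, had a median of −0.45 over 37 genes, 25 of them lower (adjusted p = 5.72e-05), with the fibronectin gene FN1 at −0.91 ± 0.28, SPARC at −0.93 ± 0.29 and LOXL1, which crosslinks elastin, at −1.23 ± 0.42. A second FN1 probe had a change of −0.10. All 24 cell cycle genes had a change below 0 (median −0.63, adjusted p = 4.55e-08), among them STMN1 at −1.05 ± 0.27, the cyclin gene CCNA2 at −1.04 ± 0.36, AURKB at −1.08 ± 0.41 and CDCA3 at −1.82 ± 0.71. The cell cycle score was 1.16 and 0.55 on CL-side autumn replicates 2 and 1, and between −0.36 and −0.08 on the other 10 arrays. Adjusted over the list alone, 5 stroma members and 0 of the other lists here passed. Without the dim array the medians were −0.44 for stroma, −0.40 for the matrix and −0.49 for the cell cycle, and the changes of PDGFRA and SPARC were −0.79 and −0.58. Without CL-side summer replicate 3 stroma had −1.23, and without CL-side autumn replicate 3 the cell cycle had −1.1 and CDCA3 −2.85. CCNA2, AURKB and CDCA3 had −0.56, −0.64 and −0.98 without CL-side autumn replicate 2. In the authors' values OGN had −0.92 and PDGFRA −0.88.

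Immediate early genes, the transcripts that cells induce within minutes of a stimulus, were higher on the CL side in summer at the preset correlation, with all 15 above 0 and a median of 1.14 (adjusted p = 5.79e-05). The adjusted p was 0.501 with an estimated correlation for the immediate early genes and 0.347 for the interferon-stimulated genes. IER3 had a change of 1.03 ± 0.33, SOCS3 1.11 ± 0.42, NR4A2 2.05 ± 0.79 and IER2 1.39 ± 0.54. Immediate early scores on the CL side overlapped, at −0.412 to 1.54 in summer and −0.947 to −0.115 in autumn. Interferon-stimulated genes had a median of 0.31 over 24 genes, 21 of them higher (adjusted p = 3.84e-04), with the antiviral gene MX2 at 1.97 ± 0.45, the immunoproteasome gene PSMB9 at 0.64 ± 0.19, XAF1 at 0.54 ± 0.19 and OAS2 at 0.77 ± 0.30. Counted as adjusted over the list alone, 0 and 1 members passed. When the dim array was left out, the medians were 0.91 and 0.26, and NR4A2 and SOCS3 had changes of 1.29 and 0.65. Without CL-side summer replicate 1 the interferon-stimulated genes had 0.47. In the authors' values the median of that list was 0.21, but MX2 had 0.32, OAS2 0.047 and SOCS3 0.049.

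In this comparison 0 of 12381 probes passed limma's threshold of 0.05, and 1228 had an unadjusted p under 0.05 against 619 expected by chance, 789 of them higher and 439 lower in summer. That split was 657 and 596 after quantile normalization and 349 and 425 with the authors' values. Without the dim array the count was 678. Under a slide block 0 probes passed and 1331 had an unadjusted p under 0.05, and on the first slide alone, where the autumn arm is a single array, the numbers were 0 and 707. With slide as a block the list medians were −1.0 for stroma, −0.53 for the matrix, −0.80 for the cell cycle, 0.57 for cytokines, 0.98 for granulocytes, 0.45 for T and NK cells, 0.53 for epithelium, 1.96 for ciliated and 0.61 for squamous epithelium, 0.38 for transporters, 1.38 for immediate early and 0.39 for interferon-stimulated genes. On the first slide alone they were −0.66, −0.43, −0.69, 0.55, 0.82, 0.46, 0.30, 1.85, 0.64, 0.40, 1.20 and 0.53, in the same order. With the replicate number as a block 0 probes passed and 741 had an unadjusted p under 0.05, or 1602 with the number as a block across seasons.

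**Figure D1:**
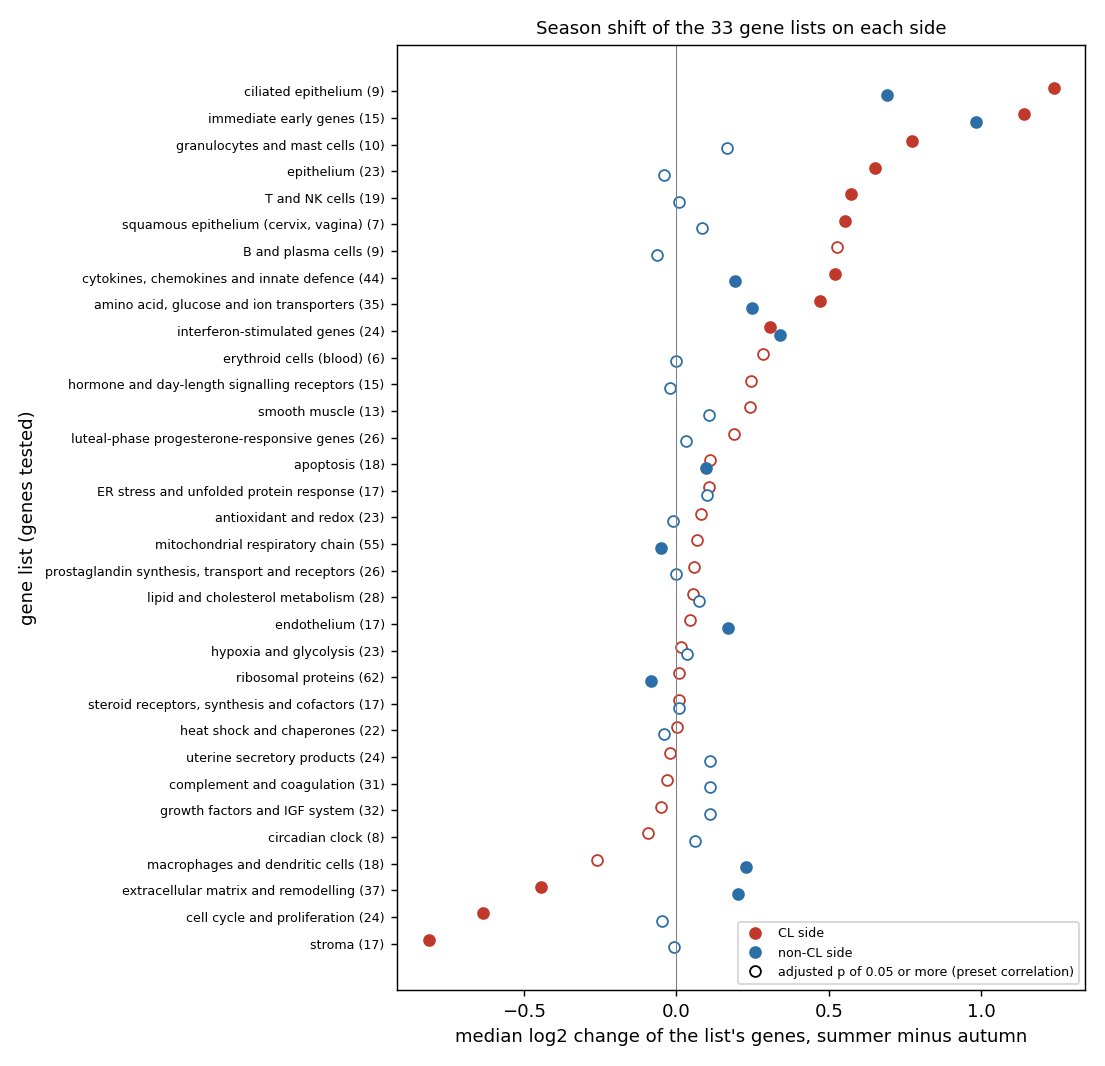
Median log2 change, summer minus autumn, of 33 gene lists with their numbers of tested genes, where red points are the CL side, blue points the non-CL side and open points have a camera adjusted p of 0.05 or more at the preset correlation. Stroma lies at −0.81 on the CL side and at −0.0093 on the non-CL side, and immediate early genes lie at 1.14 and 0.98.

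The season was then compared on the non-CL side, where interferon-stimulated genes again had higher values in summer at the preset correlation. The list had a median of 0.34 over 24 genes, 22 of them higher (adjusted p = 1.92e-12). The adjusted p was 0.190 with an estimated correlation for this list and 0.454 for immediate early and ciliated genes. ISG15, a ubiquitin-like protein that the endometrium makes in response to interferons, had a log2 signal of 1.12 ± 0.38 (SD, n = 3) in summer and 0.0073 ± 0.52 (SD, n = 3) in autumn, a change of 1.11 ± 0.32 (SE). The antiviral genes RSAD2, OAS1X and MX1 had changes of 0.63 ± 0.19, 1.17 ± 0.39 and 0.66 ± 0.26. All 15 immediate early genes were above 0 (median 0.98, adjusted p = 7.54e-08), with DUSP1 at 1.15 ± 0.57 and CCN1 at 2.18 ± 1.16. Immediate early scores on the non-CL side were −1.28, 0.89 and 1.47 in summer, and the lowest lay under all 3 autumn scores. The median was 0.44 without summer replicate 3 and 1.76 without summer replicate 1. All 9 ciliated markers were above 0 (median 0.69, adjusted p = 2.59e-04), with TEKT1 at 0.90 ± 0.62 and TPPP3 at 0.46 ± 0.27. Without autumn replicate 1 the ciliated list was not called (0.27, adjusted p = 0.248), and without autumn replicate 3 its median was 1.26. Interferon-stimulated genes had 0.21 without summer replicate 2 and stayed called. Of the genes, MX1 had 0.43 without autumn replicate 2, DUSP1 0.61 without summer replicate 3 and 1.80 without summer replicate 1, and CCN1 3.41 without summer replicate 1. TPPP3 had 0.27 and 0.70 without autumn replicates 1 and 3, and TEKT1 0.40 and 1.59 without autumn replicates 2 and 3 and 0.45 with the authors' values.

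Other lists called at the preset correlation on the non-CL side had smaller medians. The adjusted p with an estimated correlation was 0.491 for the matrix, 0.582 for macrophages, 0.817 for ribosomal proteins and the respiratory chain, and 0.454 for cytokines, transporters, endothelium and apoptosis. Higher in summer were cytokines, chemokines and innate defence (0.19, adjusted p = 3.04e-04), with CXCL3 at 1.15 ± 0.59 and the eosinophil chemoattractant gene CCL11, transporters (0.25, adjusted p = 0.0147), the extracellular matrix (0.20, adjusted p = 6.03e-04) with the thrombospondin gene THBS1 at 0.86 ± 0.37, endothelium (0.17, adjusted p = 0.00281), macrophages and dendritic cells (0.23, adjusted p = 0.00559) with CD83 at 0.62 ± 0.33, and apoptosis (0.096, adjusted p = 0.0295). CCL11 was not well above background on any non-CL-side autumn array and was at least 3.77-fold higher in summer, with an adjusted p of 1. Ribosomal protein genes (median −0.083 over 62 genes, adjusted p = 8.49e-04) and genes of the mitochondrial respiratory chain (−0.051 over 55 genes, adjusted p = 0.0364) were lower, with RPL12 at −0.44 ± 0.17 and NDUFV2 at −0.50 ± 0.20. With 1 array left out the calls ended for transporters without summer replicate 2 (0.10, adjusted p = 0.0661), summer replicate 3 (0.081, 0.108) or autumn replicate 1 (0.23, 0.248), and for apoptosis without these or autumn replicate 2 (0.00059, 0.208). They ended for the matrix without summer replicate 2 (0.069, 0.0536) or autumn replicate 3 (0.16, 0.105), and for endothelium without summer replicate 1 (0.14, 0.139) or autumn replicate 3 (0.14, 0.249). They also ended for macrophages without summer replicate 1 (0.18, 0.107) or autumn replicate 2 (0.071, 0.185), and for ribosomal proteins without autumn replicate 2 (−0.027, 0.185). The respiratory chain was called only with either replicate 2 left out, and cytokines stayed called throughout, with 0.10 to 0.37. Of single genes, BAX, which promotes apoptosis, had a change of 0.68 ± 0.20. GMPS, an enzyme of guanine nucleotide synthesis, had −0.64 ± 0.16, CDC45, a replication factor, −1.07 ± 0.34 and UBE2E3 −0.71 ± 0.22. DCAF16 (−1.16 ± 0.21) and HNRNPK (−0.51 ± 0.18) were well above background on 3 of 3 autumn arrays and on 1 and 2 of 3 summer arrays. Without autumn replicate 2 CXCL3 had 0.73, CD83 0.34 and CDC45 −0.66, without autumn replicate 3 HNRNPK had −0.32, and without summer replicate 3 CXCL3 had 0.68. In the authors' values CCL11 had 0.51, CDC45 −0.27, UBE2E3 −0.42, DCAF16 −0.28 and HNRNPK −0.15.

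On the non-CL side 0 of 12383 probes passed limma's threshold, the smallest adjusted p was 1, and 139 probes had an unadjusted p under 0.05 against 619 expected by chance. With the replicate number as a block 0 passed and 402 did, or 244 with the number as a block across seasons. Adjusted over the list alone, 0 members of these 11 lists passed. With slide as a block the medians were 0.39 for interferon-stimulated, 1.1 for immediate early and 1.36 for ciliated genes, 0.28 for cytokines, 0.12 for apoptosis and 0.30 for macrophages. The calls ended with that block for transporters (0.13), the matrix (0.10), endothelium (0.11), the respiratory chain (−0.033) and ribosomal proteins (0.00048). On the first slide alone the autumn arm is a single array, whose spread is taken from the other groups. There interferon-stimulated (0.21), immediate early (1.28), ciliated (1.57) and transporter (0.16) genes were called, and macrophages (0.025), cytokines (0.12), endothelium (0.23), the matrix (0.15), apoptosis (0.15), the respiratory chain (−0.064) and ribosomal proteins (−0.13) were not. Under the replicate block the call for the respiratory chain ended (−0.050, adjusted p = 0.0764), as it did with the authors' values (−0.048, 0.0753), where the transporters had 0.085 and cytokines 0.13.

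**Figure D2:**
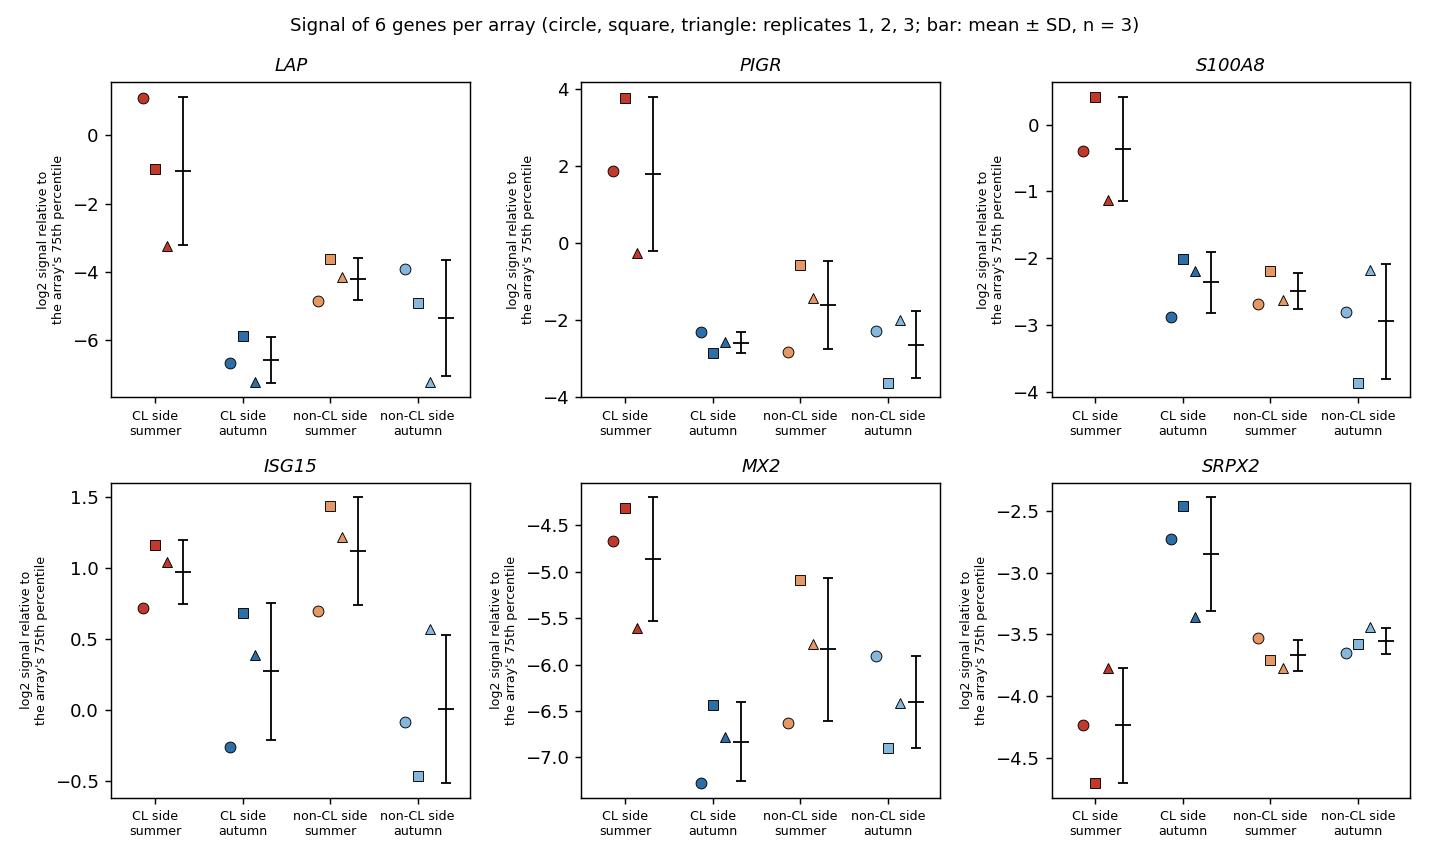
Log2 signal of 6 genes relative to the array's 75th percentile on the vertical axis, by group on the horizontal axis, where circles, squares and triangles are replicates 1, 2 and 3 and bars are the mean ± SD of 3 arrays. LAP lies between −3.25 and 1.11 on the CL-side summer arrays and between −7.23 and −5.89 on the CL-side autumn arrays.

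Averaged over both horns, 11 lists were called between the seasons at the preset correlation. Camera with an estimated correlation gave an adjusted p of 0.466 for immediate early genes and the 3 epithelial lists and 0.432 for the other 7. The lower values of stroma and the cell cycle came from the CL side, as their scores changed by −0.0079 and −0.058 on the non-CL side. Epithelium, T and NK cells, granulocytes and squamous epithelium were not called on the non-CL side either. Their scores changed there by −0.020, 0.056, 0.13 and 0.15, against 0.61, 0.64, 1.06 and 1.32 on the CL side. The medians over both horns were 0.28 for interferon-stimulated genes (adjusted p = 1.73e-07), 1.15 for immediate early genes (1.73e-07), 0.34 for cytokines (6.36e-08), 0.42 for transporters (5.38e-04), 0.96 for ciliated epithelium (5.38e-04), 0.33 for epithelium (5.38e-04), 0.40 for granulocytes (0.00554), 0.34 for squamous epithelium (0.00554), 0.36 for T and NK cells (0.00111), −0.47 for stroma (1.73e-07) and −0.34 for the cell cycle (1.73e-07). The genes with the smallest p were DHRS9, a dehydrogenase of retinoids and steroids (0.74 ± 0.14), LAP (3.35 ± 0.67), MX2 (1.27 ± 0.28), the oxysterol receptor gene GPR183 (0.59 ± 0.13) and IL1RN, the interleukin-1 receptor antagonist (0.57 ± 0.13). Lower were SRPX2 (−0.75 ± 0.18), RAB26 (−0.59 ± 0.14), GMPS (−0.59 ± 0.15), AP1S1 (−0.83 ± 0.21) and MRPS7 (−1.09 ± 0.29), a gene of the mitochondrial ribosome that was well above background on 1 of 3 CL-side summer arrays and on 2 of 3 in 2 other groups. DHRS9 had −0.0073, MX2 0.21, LAP 2.02 and MRPS7 −0.40 in the authors' values.

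Of the 12 fixed genes, ISG15 had a change of 0.91 ± 0.23 over both sides, and PTGS2, the inducible prostaglandin synthase, had 0.84 ± 0.38, or 0.39 without replicate 2 of autumn. HSPA8 had −0.24 ± 0.13, HSP90AA1 0.0062 ± 0.15, HSPB1 −0.0044 ± 0.21 and SOD1 −0.037 ± 0.13. The stress-induced heat shock gene HSPA1A had −0.43 ± 0.27 on its probe measured on all 12 arrays, since its brightest probe was measured on 2. The receptor genes PGR, ESR1 and OXTR had −0.19 ± 0.16, 0.16 ± 0.27 and −0.10 ± 0.96, and the prostaglandin genes PTGES and AKR1B1 had 0.27 ± 0.45 and −0.27 ± 0.45, with AKR1B1 measured on 2 of 3 CL-side autumn arrays. OXTR had −0.54, PTGES −0.17 and AKR1B1 0.13 without the dim array, so the signs of PTGES and AKR1B1 changed in that fit. There summer number 2 was its non-CL side alone, so a difference between the sides may also enter these values. The signs of HSP90AA1, HSPB1, SOD1, ESR1 and OXTR also changed when a number was left out of 1 season. The adjusted p of these genes was 0.895 or more. Heat shock and chaperone genes had a median of −0.056 over 24 genes (camera adjusted p = 0.583), with medians of 0.0028 on the CL side and −0.039 on the non-CL side. Fry called 0 lists by direction in every comparison, with a smallest adjusted p of 0.0849 on the CL side. By its mixed p it called 1 list, heat shock over both sides, and 0 on genes measured on all 12 arrays.

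Lists with no call in any comparison had the following season medians over both sides. These were 0.020 for antioxidant and redox genes, 0.053 for the unfolded protein response, 0.014 for prostaglandin genes, 0.0032 for steroid receptors and synthesis, 0.095 for luteal-phase progesterone-responsive genes, 0.064 for uterine secretory products, 0.017 for growth factors, 0.14 for hormone and day-length signalling receptors, −0.015 for the circadian clock, 0.052 for complement and coagulation, 0.054 for hypoxia and glycolysis and 0.18 for erythroid cells. Of 12391 probes 0 passed limma's threshold in this comparison, 498 had an unadjusted p under 0.05 against 620 expected by chance, and the smallest adjusted p was 0.895. With the replicate number as a block on the means 0 passed and 706 had an unadjusted p under 0.05. The count thus lay below or above the chance number depending on the pairing. The number as a block across seasons gave 1321, but that fit took both horns of a sampling as independent. Its count is therefore not comparable with the others. Counted as adjusted over the list alone, 2 granulocyte members and 1 squamous member passed. With slide as a block, which here leaves the first slide's values and so 1 autumn array per side, the medians were 0.39, 1.22, 0.51, 0.26, 1.71, 0.29, 0.49, 0.60, 0.26, −0.51 and −0.46 in the order given, and the calls for epithelium (adjusted p = 0.0656) and T and NK cells (0.147) ended. Without the dim array summer number 2 was its non-CL side alone. Stroma then had −0.18, epithelium 0.20 and T and NK cells 0.16, the last no longer called (adjusted p = 0.125). T and NK cells were not called without replicate 1 of summer either (0.15, adjusted p = 0.0814), nor with the authors' values (0.014, 0.176). The lowest medians with a number left out in 1 season were 0.17 for transporters, 0.21 for cytokines, 0.50 for ciliated and 0.14 for squamous epithelium, while granulocytes reached 0.61 and the cell cycle −0.57. With the authors' values transporters had 0.13, cytokines 0.19 and squamous epithelium 0.14. The call for squamous epithelium ended in 1 of 22 alternatives, the estimated correlation aside.

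**Figure D3:**
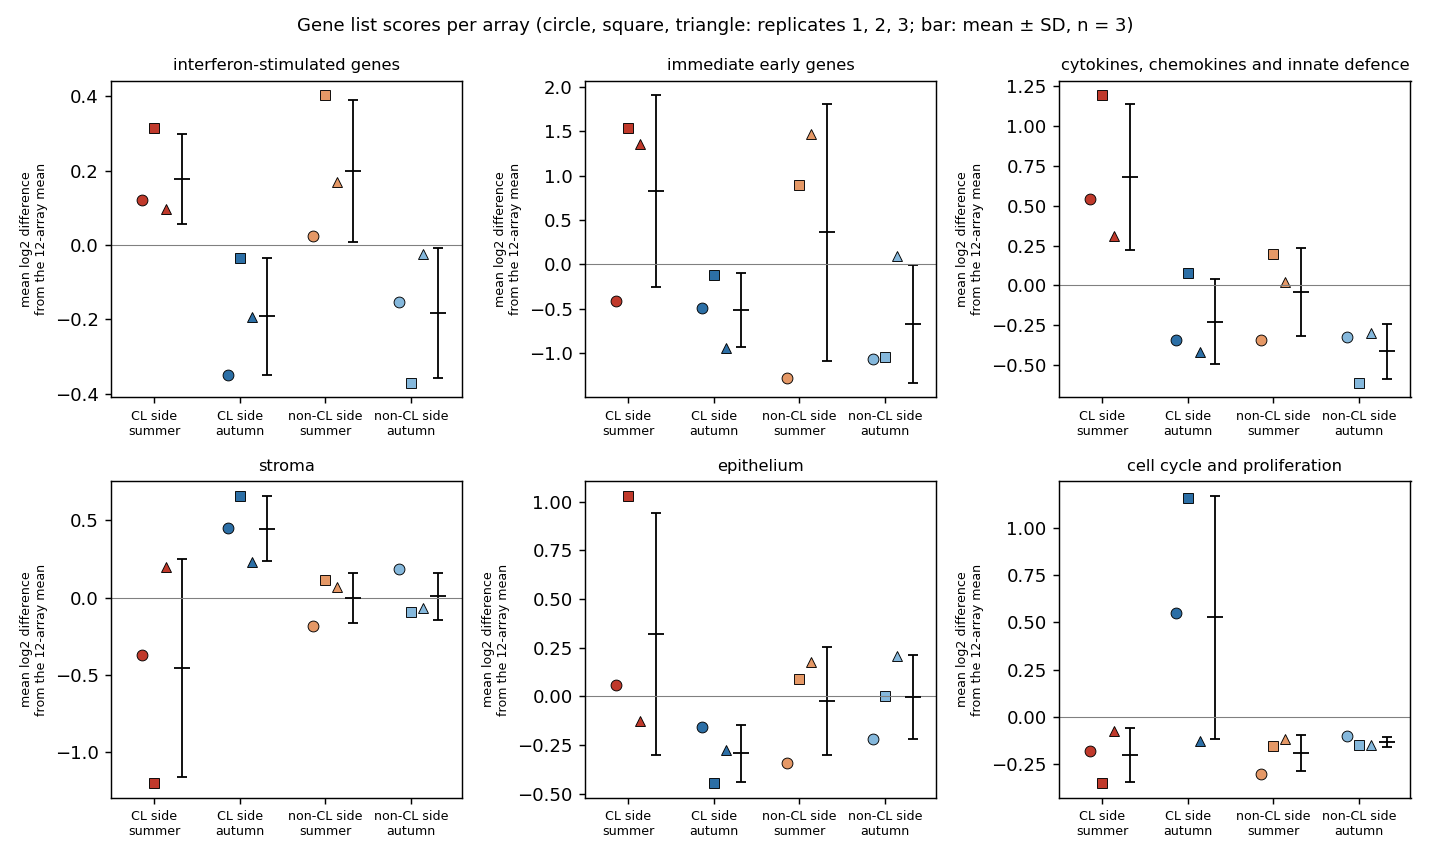
Score of 6 gene lists per array, the mean log2 difference of the list's genes from their 12-array mean, on the vertical axis, by group on the horizontal axis, where circles, squares and triangles are replicates 1, 2 and 3 and bars are the mean ± SD of 3 arrays. The stroma score of CL-side summer replicate 2 lies at −1.20, below the other 11 arrays.

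The horns were then compared within summer, which asked whether the side of the corpus luteum differed from the opposite side. Defence and granulocyte genes were higher on the CL side at the preset correlation. With an estimated correlation the adjusted p was 0.14 for granulocytes, 0.287 for T and NK cells, 0.355 for cytokines, 0.425 for squamous epithelium, 0.813 for the respiratory chain and 0.658 for the other 5 lists called at the preset value. S100A8 had a log2 signal of −0.37 ± 0.78 (SD, n = 3) on the CL side and −2.50 ± 0.27 (SD, n = 3) on the non-CL side, a change of 2.13 ± 0.47 (SE). BCL2L15 had a change of 1.15 ± 0.27, VNN1, a pantetheinase, 2.42 ± 0.59, PIGR 3.40 ± 0.89 and the cytochrome gene CYP4B1 4.65 ± 1.30. Lower on the CL side were CBX1 (−1.08 ± 0.32), DHX57 (−0.79 ± 0.28) and PODXL (−0.54 ± 0.18, measured on 2 of 3 CL-side arrays). DHX57 had −0.49 without the dim array, and PODXL was left with 1 CL-side array. RBBP7 and STRA6 were measured on 1 array per side, on the CL side the dim array, and give no estimate. In the authors' values CBX1 had 0.042. Cytokines, chemokines and innate defence (median 0.43 over 44 genes, adjusted p = 7.36e-07) had S100A12 at 1.62 ± 0.49, CXCL5 at 2.83 ± 0.90 and LAP at 3.18 ± 1.05. Granulocytes (0.91 over 10 genes, adjusted p = 2.63e-04) had LTF at 4.11 ± 1.45, and T and NK cells (0.60 over 19 genes, adjusted p = 7.36e-07) had CD69 at 0.77 ± 0.27. Ribosomal proteins (0.26 over 62 genes, adjusted p = 1.12e-11), B and plasma cells (0.43, adjusted p = 0.0261), squamous epithelium (0.32, adjusted p = 0.00265), epithelium (0.25, adjusted p = 0.00809) and the respiratory chain (0.10, adjusted p = 0.00372) were higher on the CL side, and stroma (−0.35, adjusted p = 2.49e-05) and the matrix (−0.24, adjusted p = 0.00482) lower.

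When the dim array was left out, the calls for ribosomal proteins (median 0.034, adjusted p = 0.195), stroma (−0.091, 0.272), epithelium (0.020, 0.520), B and plasma cells (0.11, 0.354) and the respiratory chain (0.042, 0.0659) ended. The medians were then 0.090 for cytokines, 0.42 for granulocytes, 0.27 for T and NK cells, 0.21 for squamous epithelium and −0.15 for the matrix, and the changes of CXCL5 and LTF were 1.70 and 2.63. LTF had 2.59 without non-CL-side replicate 1 and LAP 2.10 without CL-side replicate 1. The matrix call ended without CL-side replicate 1 (−0.088, adjusted p = 0.338) or non-CL-side replicate 2 (−0.12, 0.159), the epithelium call without non-CL-side replicate 1 (0.23, 0.214) and the respiratory chain call without CL-side replicate 1 (0.053, 0.663). B and plasma cells were not called without CL-side replicate 3 (0.31, adjusted p = 0.188) or non-CL-side replicate 1 (0.21, 0.154), nor with the authors' values (0.35, 0.0799). Without CL-side replicate 3 stroma had −0.72, the matrix −0.45, epithelium 0.48 and the respiratory chain 0.18, and without CL-side replicate 1 B and plasma cells had 0.73. Adjusted over the list alone, 2 granulocyte members and 1 cytokine member passed. All 6 summer arrays lay on 1 slide. Of 12389 probes 0 passed limma's threshold, and 175 had an unadjusted p under 0.05 against 619 expected by chance. With the replicate number as a block 0 and 422 did, or 311 with the number as a block across seasons.

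Within autumn, cell cycle, matrix and stroma genes were higher on the CL side at the preset correlation. The adjusted p with an estimated correlation was 0.356 for the cell cycle and the matrix, 0.691 for stroma, 0.701 for macrophages and 0.768 for the other 3 lists called at the preset value. CTHRC1, a secreted matrix glycoprotein, had a log2 signal of −2.46 ± 1.24 (SD, n = 3) on the CL side and −4.36 ± 0.29 (SD, n = 3) on the non-CL side, a change of 1.90 ± 0.50 (SE). SERPINA14, the uterine serpin that the progesterone-exposed endometrium secretes, had a change of 3.01 ± 0.89, the perforin gene PRF1 1.38 ± 0.41, NEIL3, a DNA glycosylase, 1.65 ± 0.48 and ACAT2 0.57 ± 0.16. SERPINA14 had 1.87 on the second slide alone, where CL-side replicate 3 lay below its non-CL-side counterpart (−0.64 and −0.099). Lower were DCAF16 (−1.17 ± 0.21), the arginase gene ARG2 (−1.07 ± 0.23), TBC1D22A (−0.60 ± 0.16) and LIN7B (−0.77 ± 0.24). DCAF16 and ARG2 were well above background on 1 of 3 CL-side arrays, LIN7B on 2, and NEIL3 on 2 of 3 non-CL-side arrays. NEIL3 had 0.95 without CL-side replicate 2. In the authors' values it had 0.98, TBC1D22A had −0.12, and DCAF16 (0.26), ARG2 (0.28) and LIN7B (0.40) changed sign. Cell cycle genes had a median of 0.43 over 24 genes (adjusted p = 1.41e-09) and of 0.19 without CL-side replicate 2, with CENPF at 2.12 ± 0.67, CDCA3 at 2.04 ± 0.71, AURKB at 1.15 ± 0.41 and PRC1 at 1.41 ± 0.51. CENPF signals were −3.40 and −2.41 on CL-side autumn replicates 1 and 2 and −5.93 on replicate 3, against −6.10 to −5.92 on the non-CL side. The matrix list (0.46 over 37 genes, adjusted p = 3.99e-10) had FN1 at 0.84 ± 0.28, and all 17 stroma markers were above 0 (0.37, adjusted p = 2.94e-07), with VIM at 0.57 ± 0.22 and OGN at 1.30 ± 0.44. Macrophages and dendritic cells (0.32, adjusted p = 3.65e-04), ribosomal proteins (0.15, adjusted p = 2.22e-08) and smooth muscle (0.45, adjusted p = 0.0325) were higher, and epithelium (−0.45 over 23 genes, adjusted p = 6.70e-04) was lower, with EPCAM at −0.51 ± 0.26. Without CL-side replicate 2 EPCAM had −0.18, CENPF 1.36, CDCA3 1.19, AURKB 0.72, PRC1 0.92 and VIM 0.31, and PRC1 had 2.13 without CL-side replicate 3.

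For the sides in autumn, counted as adjusted over the list alone, 0 members of these 7 lists passed. Without CL-side replicate 2 macrophages were not called (0.096, adjusted p = 0.257, and 0.19 without non-CL-side replicate 2, still called), and stroma had 0.21, epithelium −0.21 and ribosomal proteins 0.075. The call for smooth muscle ended without replicate 1 of the CL side (−0.070, adjusted p = 0.831) or non-CL side (0.24, 0.291), without non-CL-side replicate 3 (0.14, 0.434) and with the authors' values (0.47, 0.0829). On the first slide, with 1 array per side, which allows no test of its own, the medians were 0.34 for the cell cycle, 0.31 for the matrix, 0.27 for stroma, 0.045 for epithelium, −0.14 for macrophages, −0.035 for ribosomal proteins and 2.22 for smooth muscle. On the second slide, with 2 arrays per side, they were 0.58, 0.53, 0.42, −0.58, 0.56, 0.24 and −0.28. Under a slide block every one of these medians moved by less than 0.01. The layout fixed this in advance, because each slide held as many CL-side as non-CL-side arrays. Of 12378 probes 0 passed limma's threshold, and 230 had an unadjusted p under 0.05 against 619 expected by chance. With the replicate number as a block 0 and 526 did, or 388 with the number as a block across seasons.

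Over both seasons, S100A8 (1.36 ± 0.33), BCL2L15 (0.73 ± 0.19), VNN1 (1.58 ± 0.42), PRF1 (1.05 ± 0.29) and GPR183 (0.48 ± 0.13) were the genes with the smallest p and a higher value on the CL side. Lower were ARG2 (−0.65 ± 0.17), FAM13A (−0.79 ± 0.21) and RET (−0.53 ± 0.17). ARG2 was well above background on 2 of 3 CL-side summer and 1 of 3 CL-side autumn arrays, and FAM13A on 2 of 3 in each. DCAF16 and OSCP1 were also lower, but DCAF16 in summer and OSCP1 in autumn lay at the floor on all 3 CL-side arrays, and no change is given. All 5 of these genes changed sign in the authors' values, with 0.28 for ARG2, 0.26 for FAM13A and 0.15 for RET. Camera with an estimated correlation gave an adjusted p of 0.269 for granulocytes, 0.586 for cytokines, 0.709 for smooth muscle and 0.673 for the other 4 lists called at the preset value. Ribosomal proteins had a median of 0.20, with 61 of 62 genes higher (adjusted p = 1.41e-18), among them RPS19 at 0.32 ± 0.11 and RPS15 at 0.32 ± 0.11. Cytokines and innate defence (0.26, adjusted p = 1.65e-06) with IL1RN at 0.76 ± 0.26, granulocytes (0.46, adjusted p = 0.00183), the cell cycle (0.19, adjusted p = 0.00183), T and NK cells (0.21, adjusted p = 0.00118) with CD3D at 0.32 ± 0.14, and smooth muscle (0.50, adjusted p = 0.0272) with SMTN at 0.51 ± 0.31 were higher. Lipid and cholesterol metabolism was lower (−0.14 over 28 genes, adjusted p = 0.0455), with FDFT1, a cholesterol synthesis enzyme, at −0.40 ± 0.19. Adjusted over the list alone, 2 granulocyte members and 0 of the other 6 lists passed.

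Of 12375 probes 0 passed limma's threshold for the sides over both seasons, and 205 had an unadjusted p under 0.05 against 619 expected by chance. With the replicate number as a block 0 and 452 did, or 376 with the number as a block across seasons. Without the dim array the ribosomal median was 0.097, cytokines had 0.13, T and NK cells 0.11, and smooth muscle (0.12, adjusted p = 0.237) and lipid metabolism (−0.089, adjusted p = 0.142) were no longer called, with SMTN at 0.28 (0.33 without CL-side autumn replicate 1). The cell cycle call ended without CL-side summer replicate 1 (0.14, adjusted p = 0.101) or 3 (0.16, 0.0963), and its median was 0.034 without CL-side autumn replicate 2. Smooth muscle was not called without replicate 1 of the non-CL side in summer (0.22), of the CL side in autumn (0.13) or of the non-CL side in autumn (0.21), nor without non-CL-side autumn replicate 3 (0.21). Lipid metabolism was not called without CL-side summer replicate 3 (−0.097), non-CL-side summer replicate 2 (−0.12), CL-side autumn replicates 2 (−0.10) or 3 (−0.097), or non-CL-side autumn replicates 1 (−0.11) or 3 (−0.095). Granulocytes had 0.27 without CL-side autumn replicate 3 and 0.70 without CL-side summer replicate 1. Over 27 alternatives, the estimated correlation aside, the granulocyte median ran from 0.16 to 0.71, and the call ended in 1. Of the 33 list scores, that of hormone and day-length signalling receptors was higher on the CL side in all 6 same-numbered pairs, by a mean of 0.12 (exact p = 0.0312, the smallest possible and not adjusted over the lists). Camera did not call that list. For the lists called here the exact p was 0.0938 for granulocytes, 0.125 for ribosomal proteins and for cytokines, and 0.281 for the cell cycle. It was 0.344 for lipid metabolism, 0.375 for T and NK cells and 0.438 for smooth muscle. With slide as a block lipid metabolism was no longer called (adjusted p = 0.0539). The medians did not move, which the equal numbers of CL-side and non-CL-side arrays on each slide fixed in advance. On the first slide alone, which has 1 autumn array per side, the medians were 0.11 for ribosomal proteins, 0.22 for cytokines, 0.53 for granulocytes, 0.15 for the cell cycle, 0.18 for T and NK cells, 0.97 for smooth muscle and −0.082 for lipid metabolism.

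The last comparison tested whether the season change differed between the sides. It differed for 11 lists at the preset correlation. With an estimated correlation the adjusted p was 0.355 for stroma, the matrix, the cell cycle and granulocytes, 0.375 for epithelium, squamous epithelium, T and NK cells and B and plasma cells, 0.544 for macrophages, 0.589 for cytokines and 0.910 for the respiratory chain. Stroma changed by a median of −0.81 more on the CL side than on the non-CL side (17 of 17 genes below 0, adjusted p = 4.31e-11), with COL1A1 at −1.41 ± 0.56, OGN at −1.55 ± 0.62 and VIM at −0.62 ± 0.31. The matrix (−0.56, adjusted p = 7.90e-11) with SPARC at −1.08 ± 0.42, the cell cycle (−0.60, adjusted p = 2.80e-07) with STMN1 at −0.89 ± 0.38, and macrophages (−0.44, adjusted p = 0.00666) also differed downwards. Epithelium (0.71, adjusted p = 1.08e-05) with KRT8 at 1.01 ± 0.53, T and NK cells (0.60, adjusted p = 8.67e-04) with CD3G at 1.46 ± 0.58 and GNLY at 1.42 ± 0.58, granulocytes (0.85, adjusted p = 0.0305), cytokines (0.39, adjusted p = 0.0216) with LAP at 4.42 ± 1.48, squamous epithelium (0.62, adjusted p = 0.0108) with KRT15 at 4.29 ± 1.62, B and plasma cells (0.61, adjusted p = 0.0209) and the respiratory chain (0.13, adjusted p = 0.0216) differed upwards. The genes with the smallest p were TBC1D22A (0.88 ± 0.23), LIN7B (1.14 ± 0.33), C8B (1.99 ± 0.60) and FGF4 (1.29 ± 0.40) upwards, and SRPX2 (−1.28 ± 0.37), GYG1 (−1.08 ± 0.32), FN1 (−1.25 ± 0.40) and CBX1 (−1.29 ± 0.45) downwards. C8B and LIN7B in CL-side autumn and CBX1 in CL-side summer were well above background on 2 of 3 arrays. DCAF16, at the floor on all 3 CL-side summer arrays, and RBBP7, measured on 1 summer array per side, give no estimate here. In the authors' values TBC1D22A had 0.44, C8B 0.24, FGF4 0.048, LIN7B −0.0074, GYG1 −0.53, CBX1 −0.47, CD3G 0.81 and OGN −0.89. VIM had −0.36 without CL-side autumn replicate 2.

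For the difference between the sides 0 of 12375 probes passed limma's threshold, and 233 had an unadjusted p under 0.05 against 619 expected by chance. With the replicate number as a block 0 and 548 did, or 366 with the number as a block across seasons. Counted as adjusted over the list alone, 0 members of these 11 lists passed. On genes measured on all 12 arrays the call for granulocytes ended (median 0.87, adjusted p = 0.0647). When the dim array was left out, the calls for macrophages (−0.083, adjusted p = 0.172), cytokines (0.079, 0.258), B and plasma cells (0.30, 0.0877) and the respiratory chain (0.076, 0.185) ended, stroma had −0.50, the cell cycle −0.33, epithelium 0.50, granulocytes 0.54, T and NK cells 0.49, squamous epithelium 0.47 and the matrix −0.57, and the changes of KRT8 and GNLY were 0.50 and 0.94. Without CL-side autumn replicate 3 the cell cycle had −1.0. Without non-CL-side summer replicate 1 the calls ended for squamous epithelium (0.31, adjusted p = 0.0520), cytokines (0.22, 0.0684), granulocytes (0.58, 0.0684), B and plasma cells (0.28, 0.0684) and the respiratory chain (0.085, 0.0520). Without CL-side autumn replicate 1 they ended for cytokines (0.40, 0.0832), granulocytes (0.74, 0.123), B and plasma cells (0.44, 0.0593) and the respiratory chain (0.11, 0.123), and without CL-side autumn replicate 2 for macrophages (−0.19, 0.238). Without CL-side autumn replicate 3 or non-CL-side autumn replicate 3 they ended for cytokines (0.28 and 0.27), granulocytes (0.64 in each) and the respiratory chain (0.067 and 0.11). They also ended for cytokines (0.37) and the respiratory chain (0.10) without non-CL-side autumn replicate 1, for B and plasma cells without non-CL-side autumn replicate 2 (0.56), and for B and plasma cells (0.69) and granulocytes (0.98) without CL-side summer replicate 3. The respiratory chain was not called without CL-side summer replicate 1 (0.10) or non-CL-side summer replicate 3 (0.12) either. With the authors' values T and NK cells had 0.11, granulocytes 0.46, cytokines 0.061 and B and plasma cells 0.18, the last not called (adjusted p = 0.184). Under a slide block no call of the 11 lists ended, but that block could not shift the medians, because each slide held as many CL-side as non-CL-side arrays. The first slide alone has 1 autumn array per side, so whether a call ends there is no test. Its medians were 0.37 for epithelium, 0.082 for macrophages, 0.62 for squamous epithelium and 0.16 for the respiratory chain. Stroma had −0.50, the matrix −0.44, the cell cycle −0.36, granulocytes 0.86, T and NK cells 0.89, cytokines 0.57 and B and plasma cells 1.12. Under the replicate block the call for the respiratory chain ended (0.13, adjusted p = 0.0533). Across 12375 probes, which are not independent replicates, the season changes of the sides correlated at 0.349 and 61.6% had the same sign. Same-numbered horns of a season deviated together, so such a correlation can arise without a season effect.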

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

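The tests of the dim array, the slide, the tissue composition, leukocytes and shared handling were chosen after the results they address were seen, and the splits of the samples were planned.

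The season change differed between the sides, by a test of the difference itself, for 11 gene lists at the preset correlation. The median difference was −0.81 for stroma, −0.56 for the extracellular matrix, −0.60 for the cell cycle, −0.44 for macrophages and dendritic cells, 0.71 for epithelium, 0.62 for squamous epithelium, 0.60 for T and NK cells, 0.85 for granulocytes, 0.39 for cytokines, 0.61 for B and plasma cells and 0.13 for the respiratory chain. With an estimated correlation the smallest adjusted p of these lists was 0.355. Of the 10 splits of the samples, 5 gave as many lists, with 11 in the real split and 14 in the highest other, and 4 gave as many probes at an unadjusted p under 0.05, with 233 and 482. Groups of 3 were not tested for outlying samples.

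The first pattern was lower stroma and higher epithelium markers on the CL side in summer. Without the dim array the stroma score still differed by −0.532 (SE 0.264, with it −0.902, SE 0.423), just over 2 SE. With so few arrays left, a difference of that size cannot decide whether that array was the whole cause. For epithelium the difference was 0.26 without the dim array (SE 0.13) and 0.613 with it (SE 0.367), which leaves the array open too. A different share of epithelium and stroma in the biopsies stays a candidate explanation, as the scores correlated within groups at −0.756 (permutation p = 0.00857, rho −0.483, permutation p = 0.118, 1 relation computed), but r was −0.0871 without CL-side summer replicates 2 and 3 and so rested on those samples. Tissue of the cervix or vagina in the summer samples stays open too, since the score of squamous markers differed by 1.32 on the CL side and 0.148 on the non-CL side, and the defence and epithelial lists were higher on the CL side as well. The median change of the squamous markers on the CL side was only 0.55, so single genes weigh on that mean score. Slide stays open, with −0.906 (SE 0.692) for stroma and 0.475 (SE 0.589) for epithelium under a slide block, as does a season effect itself.

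The second pattern was higher interferon-stimulated genes in summer on both sides. With slide as a block the score differed by 0.439 (SE 0.149, without the block 0.375, SE 0.0967), but the block leaves replicate 1 of the horns as the autumn samples, and slide and scan stay open. More leukocytes in the summer samples stay open, because on the non-CL side the T and NK cell score differed by 0.0557 (SE 0.172, CL side 0.643, SE 0.22) and the macrophage score by 0.23 (SE 0.111, CL side −0.209, SE 0.37). A season effect may also account for the pattern and was not tested apart from these. With the authors' values, in which the low-end treatment is unknown, the direction of the list medians was the same.

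The third pattern was higher immediate early genes in summer on both sides, although the scores of the seasons overlapped on each side. The lowest summer score was −0.412 on the CL side and −1.28 on the non-CL side, and the highest autumn scores were −0.115 and 0.0968. Under a slide block the score differed by 1.37 (SE 1.18, without the block 1.19, SE 0.729), and slide stays open. Handling shared by both horns of a sampling could raise these genes, as they respond within minutes. The scores of the horns correlated within groups at 0.679 (exact p = 0.138, rho 0.543, exact p = 0.297, 0.683 without the 2 farthest), over 6 pairs, too few to settle it. A season effect stays open as well.

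With 10 splits of 3 against 3 arrays no share under 0.05 can be had, and only the values are given. For the season on the CL side 1 split, the real one, reached 1228 probes at an unadjusted p under 0.05 (highest other 1204), and 3 reached 12 lists (highest other 13). On the non-CL side 8 splits reached 139 probes (highest other 1049) and 1 reached 11 lists (highest other 6). For the mean of the sides 5 reached 498 probes (highest other 987) and 1 reached 11 lists (highest other 9). For the sides in summer 9 splits reached 175 probes (highest other 1667) and 2 reached 10 lists (highest other 10), and in autumn 9 reached 230 probes (highest other 1068) and 3 reached 7 lists (highest other 10). Splits several times the real count point to a structure of the samples, and the highest ones kept same-numbered arrays together. Among splits that part as many same-numbered pairs as the real one, the highest other count was 650, 346, 427, 287 and 391 in the order given, and 221 for the season by side.

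For the sides over both seasons chance was not excluded. Of 100 drawn splits, 86 reached 205 probes (highest other 1763, or 453 among those parting as many pairs) and 42 reached 7 lists (highest other 15). Exchanging the horns of same-numbered pairs gave 32 splits, of which 16 reached 452 probes (highest other 833) and 18 reached 9 lists (highest other 14).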

How the results depend on the processing

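The fit without the dim array, the second slide alone, array weights, the higher floor, list genes measured on all 12 arrays and the replicate number as a block across seasons were chosen after the data were seen. Under limma's main setting 0 genes passed in each of the 7 comparisons, and over all alternatives 169 of these gene counts stayed the same and 9 moved. With an estimated correlation 0 lists were called in each comparison, against 12, 11 and 11 for the season on the CL side, the non-CL side and their mean, 10, 7 and 7 for the sides in summer, autumn and their mean, and 11 for the season by side.

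For the season on the non-CL side 6 lists were called with slide as a block and 5 on the first slide alone, where 1 gene passed and autumn is a single array. For the sides in autumn the first slide holds 1 array per side, and the 3 lists called there are no test of the main result. Without a filter on dim probes 4 lists were called for the sides over both seasons and 7 for the season by side, and without the dim array 11 for the sides over both seasons.

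Leaving out each replicate gave 0 to 7 genes for the season on the CL side (7 without CL-side autumn replicate 3, 4 without CL-side summer replicate 3, 2 without CL-side summer replicate 1), 0 to 2 for the mean of the sides (2 without summer replicate 1) and 0 to 6 for the sides in autumn (6 without CL-side autumn replicate 3). It gave 0 to 1 for the sides in summer, the sides over both seasons and the season by side (1 without CL-side summer replicate 3 in each). Lists called ranged from 6 to 11 for the sides over both seasons and from 7 to 12 for the season by side.

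Of the list shifts, 1463 kept camera's direction and their side of the threshold, 217 were weaker and 4 reversed in camera's direction, all 4 for the sides in autumn. The 217 hold every called list once for the estimated correlation, where no list was called. Epithelium had 0.0447 and macrophages −0.136 on the first slide alone, and smooth muscle had −0.275 on the second slide alone. Without CL-side autumn replicate 1 smooth muscle had −0.0697, in a range of −0.0697 to 0.796 over the replicates left out. In 3 of the weaker shifts the median changed sign while camera's direction stayed. These were ribosomal proteins for the sides in autumn (−0.0353) and macrophages for the season by side (0.0820) on the first slide alone, and ribosomal proteins for the season on the non-CL side (0.000484) with slide as a block. The cause was not tested. Of the values of named genes, 8327 kept their sign and did not pass the threshold, whatever their size. Another 111 changed sign, and 6 kept their sign and passed the threshold.

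With the replicate number as a block 0 genes passed in every comparison. The block ended the respiratory chain calls named in the report and no other list call. Unadjusted counts ranged from 676 to 1602 for the season on the CL side, 90 to 982 on the non-CL side and 333 to 1321 for the mean. They ranged from 77 to 422 for the sides in summer, 151 to 623 in autumn, 146 to 473 over both and 97 to 548 for the season by side. The count of 1321 came from a fit that took both horns of a sampling as independent. Leaving out each replicate gave 678 to 2084, 56 to 368, 209 to 929, 77 to 1060, 135 to 462, 121 to 549 and 123 to 740 in the same order. Between 12043 and 12785 probes per array were well above background, and changes in dimmer probes are limited by that.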

Other observations

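The tests in this part were chosen after the pattern was seen, and the genes named were chosen after their values were seen.

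Across the 4 groups, 136 probes differed by replicate number at a limma adjusted p under 0.05, 65 of them with a symbol. In autumn number 1 lay on slide 1 and numbers 2 and 3 on slide 2, and the fit had no slide term. Slide may therefore have added to this count, though all summer arrays lay on slide 1. PRSS2 had log2 signals of −7.28 to −7.01 on the 4 arrays of number 1, 2.18 to 2.65 on those of number 2 and 2.51 to 2.60 on those of number 3, and was well above background on 2 of the 4 arrays of number 1. BOLA-DRB2, a class II histocompatibility gene, had −6.78 to −6.28, −3.58 to −3.08 and −3.43 to −2.28. BOLA-DQB1 had 0.72 to 0.96, −1.40 to −0.41 and −1.19 to −0.89, and BOLA-DQA2 had −3.03 to −2.80, −2.07 to −1.60 and −1.77 to −1.58.

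A candidate explanation is that each number marks the same cow in both seasons, with sequence variants under some probes. When numbers were shuffled within 3 of the 4 groups, 1 of 100 orders, the real one, reached 136 probes, and the highest other reached 98. This shuffle also parts the horns of a season and parts the numbers from the slides of autumn. It does not show by itself that the numbers match across seasons. The 100 probes that differed most by number in summer had a correlation of 0.756 in autumn under the real numbers, and at most 0.572 under the others of 6 numberings that keep the horns together, where the smallest possible share is 1 of 6. If the numbers mark the same animals, the summer and autumn samples were not independent, and the fit with the number as a block is the one that allows for it.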
